A study of Arabidopsis thaliana with 9 samples.

How the data were processed

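The material was sperm nuclei of Arabidopsis thaliana htr10 mutant plants, sorted by FACS after SYBR Green staining. HTR10 (AT1G19890, also called MGH3) encodes a histone H3 of the male gamete. Per the labels' protocols, mononucleosomes were released with micrococcal nuclease and immunoprecipitated with antibodies against H3K27me1 or H3K27me3. Libraries were sequenced as 50 bp paired-end reads. The series held 9 samples, with 3 immunoprecipitations per mark and 3 inputs of digested chromatin. The sample titles number the samples of each kind 1 to 3, and per the labels each immunoprecipitation came from the input of the same number. The same labels also call every immunoprecipitation replicate 1, so the pairing is uncertain, and it was not used.

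The data analysed were 4 peak lists, a broad and a narrow list for each mark. The submitters' processing notes name Trim Galore 0.4.1, Bowtie2 2.1.0, SAMtools 1.3, Picard, bedtools, deepTools 2.5.0.1, MACS2 2.1.0 and the build TAIR10, with no role or order. Each list is named in the labels of all 3 immunoprecipitations of its mark. How the 3 samples and the inputs entered the peak calling is not given in the sources used here, nor is the treatment of reads that map to several places. The lists carry no value per sample, so no spread between samples could be computed. Sequencing depth is unknown for the same reason. From the column layout, each deposited peak has a fold enrichment, which is a ratio over the peak caller's background, and a −log10 q-value. Both are the authors' values, and they were used only to describe, rank or filter peaks within a list. The lowest −log10 q in the deposited lists was 1.02 for the broad and 2.00 for the narrow lists, as cutoffs of q = 0.1 and q = 0.01 would give.

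Everything below was computed from the broad lists on nuclear chromosomes 1 to 5, with the narrow lists as an alternative. Overlapping intervals were merged before lengths were summed. Positions were compared with 1000 circular shifts, in which each list was moved by a random distance within each chromosome. The p-values from shifts are two-sided permutation p-values, and 0.001 is the smallest that 1000 shifts can give. They test positions within these lists and say nothing of the spread between samples. The same holds for p-values over genes, which are not replicates. Pericentromeres were taken as windows of whole Mb, namely 12 to 18 Mb on chromosome 1, 1 to 7 Mb on chromosome 2, 11 to 17 Mb on chromosome 3, 2 to 6 Mb on chromosome 4 and 9 to 16 Mb on chromosome 5.

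Gene names and gene intervals came from a table of 38312 genes on the assembly TAIR10.1. The files use TAIR10, so no gene coordinate is printed, and peak coordinates are those of the files, counted from 1. Overlap of peaks with genes rests on the nuclear chromosomes of both builds sharing their numbering. This was checked by sliding the narrow peaks against the genes in steps of 100 bp up to 3000 bp either way. The share of their bases in protein-coding genes was lowest at an offset of 0 bp in 20 of 20 combinations of mark, chromosome and left or right part of the chromosome. The table gives neither strand nor exons and has no class for transposable elements. Exons, introns, untranslated regions, transposable elements and a separate upstream side of genes were therefore not counted apart. Each base was instead assigned once, to a protein-coding gene, another annotated gene, the 1 kb next to a gene, the stretch from 1 to 5 kb, or farther away.

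A protein-coding gene was counted as marked when at least 50% of its annotated length lay under merged broad peaks, among 27444 nuclear protein-coding genes. Overlap of marked genes was tested with a two-sided Fisher exact test over genes. Genes marked by 1 mark alone were compared with an exact McNemar test. For 13 gene lists with 162 entries and 158 different genes, all loci were found, and members were compared with all other genes by two-sided Fisher exact tests. Benjamini-Hochberg adjustment covered all 26 tests. The lists were Polycomb subunits, H3K27 demethylases and monomethyltransferases, flowering time, floral organ identity, embryo regulators, seed storage, meristem, YUC auxin synthesis, imprinted endosperm genes, sperm genes, vegetative cell genes of pollen, photosynthesis and housekeeping genes. Shares of genes have Wilson 95% intervals, which cover counting error only.

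Gene lists, windows, tests and the rule for naming genes were fixed before the data were examined. The rule named, for each mark, the 10 marked genes touched by the broad peak with the highest fold, at most 1 gene per peak. It added the 5 genes with the best ranks in both marks, up to 4 members of each list, and HTR10. The list members were taken in equal number as the most covered under each mark, with ties broken by locus. A named member can therefore have no coverage where few members of its list had any under 1 of the marks. This gave 52 different genes. The profile around gene edges, the location of stretches and genes under a single mark, the shift test of gene classes other than protein-coding ones, and the count of listed genes with at least 1 covered base under a single mark were added afterwards, as were McNemar tests under other settings, the random exchange of the marks within bins and the count of leading genes in the narrow lists. Alternatives were the narrow lists, peaks with a −log10 q of at least 5, the 50% of each list with the highest fold, merging across gaps of up to 500 bp, other gene thresholds, other windows, shifts within arms and pericentromeres, lists of equal length, reciprocal overlap, random lists matched on gene length, and genes outside the windows.

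The shift test and the gene-list test were tested on simulated data. With independent simulated peak lists, 1 of 20 trials gave p under 0.05, and with a planted share of common peaks 20 of 20 did. Among 200 simulated lists of 15 genes drawn from the 27444 genes, the test called 0% of unchanged lists, 49% of lists with 30% planted marked members and 96% with 50% planted. The simulated peaks were spread evenly, without the clustering near centromeres or avoidance of genes of the real lists. Outside the planted lists, every simulated gene had the same chance of being marked, whatever its length. Error rates on the real lists may therefore differ. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.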

Results

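H3K27me1 and H3K27me3 were mapped in the chromatin of sperm nuclei from htr10 mutant plants. The 2 marks are mono- and trimethylation of the same histone H3 lysine. In Arabidopsis, H3K27me1 is known from silent heterochromatin and H3K27me3 from genes repressed by Polycomb. Each mark had 3 immunoprecipitated samples and there were 3 inputs, and the peak lists analysed held 1 set of peaks per mark. There was therefore no replicate error for any value below, and the depth of the samples is unknown. No other genotype was analysed here, so the values describe htr10 sperm and not the effect of the mutation. Neither mark had a broad peak on HTR10 itself, with 0% of the gene covered. A peak list cannot show whether the gene was disrupted.

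Both marks formed many short domains of modest enrichment. H3K27me1 had 11898 broad peaks covering 20.5 Mb, or 17.2% of the 119.1 Mb spanned by chromosomes 1 to 5. H3K27me3 had 12927 broad peaks covering 20.4 Mb, or 17.1%. The median H3K27me1 peak was 1168 bp wide (quartiles 624 and 2155 bp) and the median H3K27me3 peak 1122 bp (quartiles 615 and 1997 bp). The authors' fold enrichment had a median of 1.57 for H3K27me1 (quartiles 1.48 and 1.68, highest 3.55). For H3K27me3 the median was 1.64 (quartiles 1.54 and 1.75, highest 3.88). The lists were called separately, so these folds were not compared between marks. A −log10 q of at least 5 was reached by 2331 H3K27me1 peaks (19.6%) and 1609 H3K27me3 peaks (12.4%). The narrow lists held 9451 peaks over 7.19 Mb for H3K27me1 and 8940 peaks over 5.94 Mb for H3K27me3. All of their bases, 100% for both marks, lay inside broad peaks of the same mark. A narrow peak was found in 57.4% of H3K27me1 and 52.9% of H3K27me3 broad peaks.

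The marks occupied largely the same places. Broad peaks of both marks shared 15.8 Mb, which was 76.8% of the H3K27me1 and 77.3% of the H3K27me3 territory. Circular shifts of the H3K27me3 peaks gave a mean of 3.57 Mb (SD 0.26 over 1000 shifts), so the shared length was 4.42 times the shifted one (permutation p = 0.001, the smallest the shifts can give). At least 1 bp of the other mark lay under 86.5% of H3K27me1 peaks and 81.8% of H3K27me3 peaks. Peaks of 1 mark alone were mostly weak ones. Among the 10% of H3K27me1 peaks with the lowest −log10 q, 39.7% (Wilson 95% interval 37.0 to 42.5%) had no base of H3K27me3, against 1.85% (1.22 to 2.78%) among the 10% with the highest. For H3K27me3 these shares were 53.3% (50.6 to 56.0%) and 3.48% (2.61 to 4.63%). By −log10 q, the strongest H3K27me1 peak without H3K27me3 lay on chromosome 5 from 11623506 to 11623844 (TAIR10), with a fold of 2.15 and a −log10 q of 13.8. Its H3K27me3 counterpart lay on chromosome 3 from 8374988 to 8375297, with a fold of 2.24 and a −log10 q of 9.27. Those intervals were picked after their values were seen.

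Both marks gathered around the centromeres, and H3K27me1 had the larger share there on every chromosome. The pericentromere windows made up 24.3% of the span and held 46.4% of H3K27me1 territory, 1.89 times the shift mean of 24.6% (SD 5.65, permutation p = 0.001). They held 38.1% of H3K27me3 territory, 1.55 times the shift mean (24.6%, SD 3.86, permutation p = 0.001). With windows 1 Mb shorter on each side, the H3K27me3 ratio was 1.33 and no longer passed the threshold (permutation p = 0.056). Inside the windows 32.9% of bases lay under H3K27me1 and 26.8% under H3K27me3, against 12.2% and 14.01% outside. The window share of H3K27me1 exceeded that of H3K27me3 on 5 of 5 chromosomes, by a mean of 8.16 percentage points (SD 1.96, n = 5 chromosomes, exact two-sided sign-flip p = 0.0625, the smallest 5 chromosomes allow). Chromosome 5 had the widest gap, with 49.9% and 39.5%, and chromosome 4 the narrowest, with 37.9% and 32.2%.

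**Figure D1:**
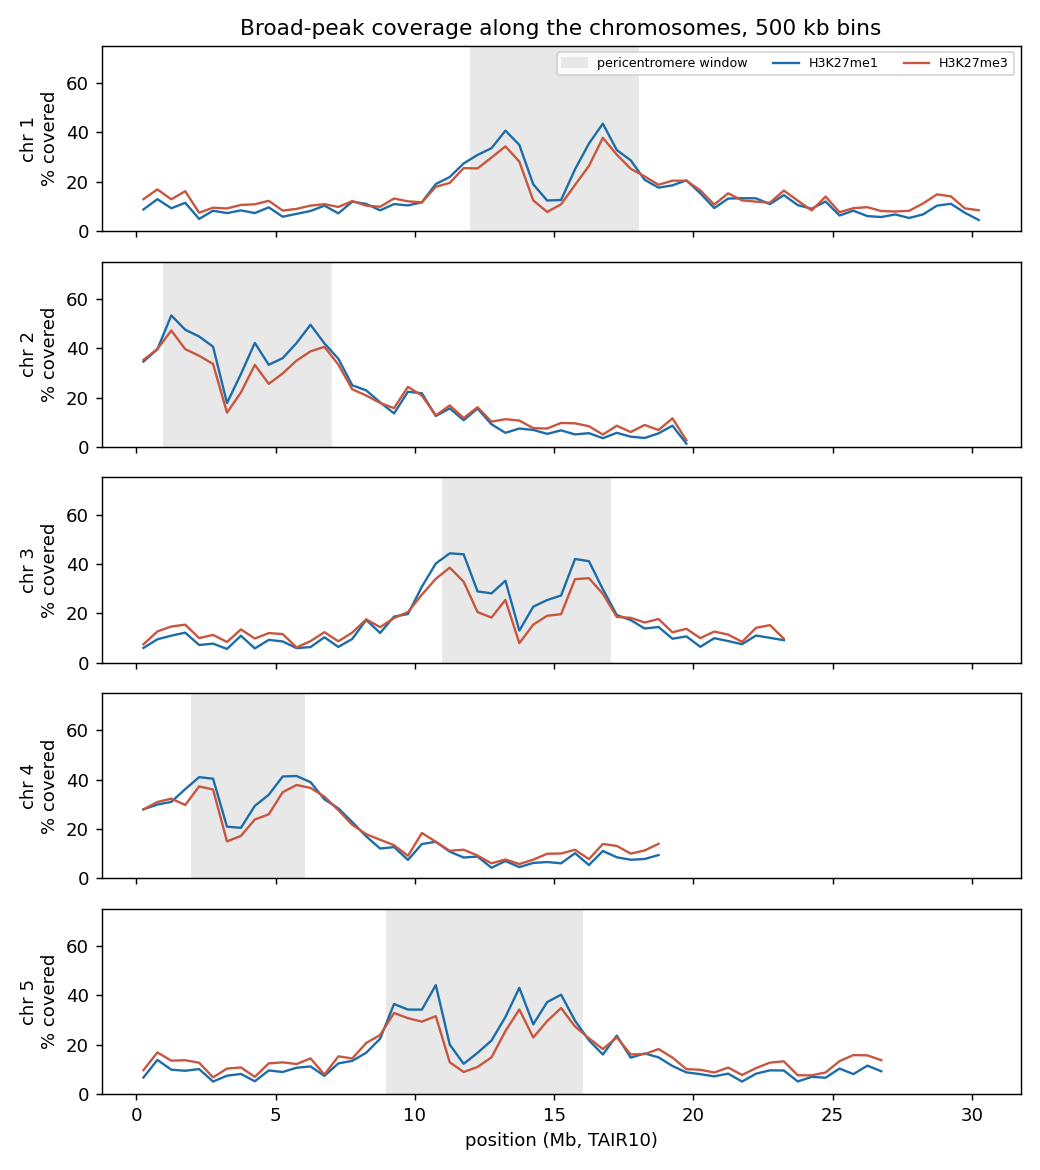
Percent of each 500 kb bin under broad peaks (y axis) along chromosomes 1 to 5 (x axis, Mb), with H3K27me1 in blue, H3K27me3 in red and the pericentromere windows in grey. Both lines rise in and beside the windows and dip near the middle of them. In the windows as a whole 32.9% of bases lay under H3K27me1 and 26.8% under H3K27me3, and H3K27me3 lies slightly above H3K27me1 over much of the arms.

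The stretches held by a single mark differed in how much of their length lay near centromeres. They were taken base by base, as 12071 stretches for H3K27me1 and 12182 for H3K27me3. Only 1608 H3K27me1 and 2359 H3K27me3 peaks had no base of the other mark. Most stretches, by number, were therefore parts of peaks that also held the other mark. H3K27me1 without H3K27me3 covered 4.77 Mb, of which 49.1% lay in the windows, close to the 45.6% of stretches under both marks. H3K27me3 without H3K27me1 covered 4.63 Mb, of which 12.4% lay in the windows. The difference had the same direction on 5 of 5 chromosomes and ranged from 26.6 to 42.7 percentage points (mean 36.3, SD 7.70, n = 5 chromosomes, exact two-sided sign-flip p = 0.0625). Protein-coding genes made up 30.4% of the H3K27me3-only stretches, 24.0% of the H3K27me1-only stretches and 15.3% of the shared ones.

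Peaks of both marks lay beside genes more than in them. Protein-coding genes held 17.3% of H3K27me1 territory against a shift mean of 53.8% (SD 3.02), a ratio of 0.32. For H3K27me3 the share was 18.7% against 53.9% (SD 2.07), a ratio of 0.35 (permutation p = 0.001 for both). The narrow lists gave lower ratios, 0.19 for both marks. Sequence within 1 kb of a gene held 49.0% of H3K27me1 and 50.3% of H3K27me3 territory, 1.97 and 2.02 times the shift means (permutation p = 0.001 for both). Sequence 1 to 5 kb from a gene held 26.5% and 25.6%, or 2.61 and 2.52 times the shift means (permutation p = 0.001 for both). Annotated genes other than protein-coding ones held 5.95% of H3K27me1 (ratio 0.58, permutation p = 0.012) and 4.51% of H3K27me3 territory (ratio 0.44, permutation p = 0.001). Sequence over 5 kb from any gene held 1.17% and 0.876%, and neither passed the test (permutation p = 0.21 and 0.98). In the profile around protein-coding genes, coverage was highest 400 bp outside the gene edge, at 22.0% for H3K27me1 and 24.3% for H3K27me3. The profile also counted positions that lay in neighbouring genes, so it does not show where between genes coverage was highest. By the ratios above, enrichment was larger 1 to 5 kb from a gene than within 1 kb. Coverage fell to 3.18% and 3.30% at 1000 bp inside genes of at least 2000 bp.

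**Figure D2:**
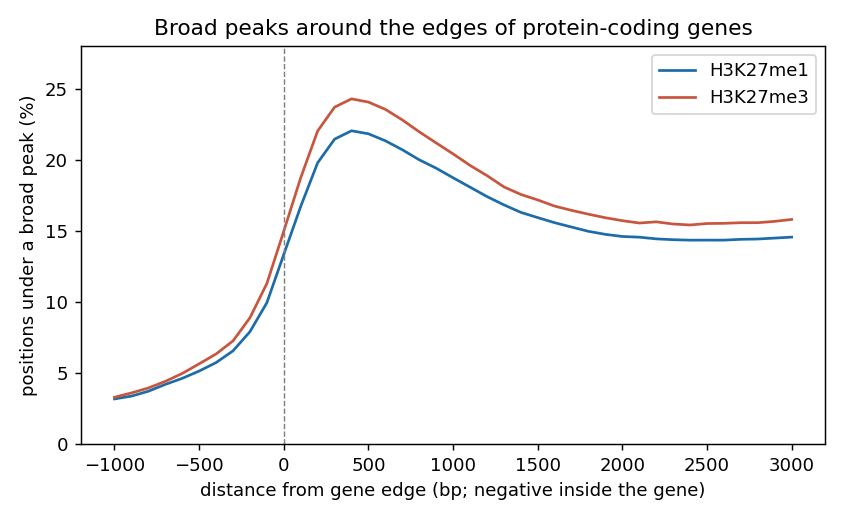
Percent of positions under a broad peak (y axis) by distance from the edges of protein-coding genes (x axis, bp, negative inside the gene, where genes of at least 2000 bp were used). The lines for H3K27me1 and H3K27me3 rise together across the edge to 22.0% and 24.3% at 400 bp outside it. Positions that lay in neighbouring genes were counted too, so the fall farther out does not describe sequence between genes alone.

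Few protein-coding genes were covered over most of their length, and the marks shared many of them. H3K27me1 marked 1507 of 27444 genes (5.49%) and H3K27me3 marked 1555 (5.67%). Both marks covered 1023 of these genes, where independent lists would share 85.4 (odds ratio 101, two-sided Fisher exact test over genes, with a p below what the arithmetic can represent). H3K27me1 alone marked 484 genes and H3K27me3 alone 532, a difference that did not pass the test (exact McNemar p = 0.14). When 1 covered base was enough, H3K27me1 reached 6219 genes and H3K27me3 7143, with 1419 and 2343 genes under 1 mark alone (exact McNemar p = 1.1e-51). At the 50% threshold, 3 stricter selections of peaks were compared with the 484 and 532. With a −log10 q of at least 5, H3K27me1 marked 465 genes and H3K27me3 238, with 290 and 63 under 1 mark alone (exact McNemar p = 6.3e-36), and the narrow lists gave 84 and 53, with 47 and 16 (exact McNemar p = 0.00012). Both selections kept more H3K27me1 territory, 6.27 against 3.49 Mb and 7.19 against 5.94 Mb. The lists were called separately at unknown depth, so a common cutoff need not be equally strict for both. These 2 differences may therefore follow from how many peaks passed. The 50% of each list with the highest fold left 384 and 373 under 1 mark alone, which did not pass the test (exact McNemar p = 0.72). Genes covered over at least 50% of their length were short, with medians of 1027 bp for H3K27me1 and 1015 bp for H3K27me3 against 2078 bp for all genes. Those with at least 1 covered base were not, with medians of 2277 and 2291 bp. At the 50% threshold, in the shortest 1370 genes 20.4% were marked by H3K27me1 and 20.7% by H3K27me3, and in the longest 1373 genes 1.68% and 0.947%. Genes under H3K27me1 alone lay in the pericentromere windows in 47.5% of cases (Wilson 95% interval 43.1 to 52.0%), and those under H3K27me3 alone in 13.7% (11.1 to 16.9%). The odds ratio between these groups was 5.69 (Fisher exact p = 9.4e-33 over genes), and 10.96% of all protein-coding genes lay in the windows.

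Among marked genes, those touched by the peaks of highest fold lay mostly in the pericentromere windows and mostly carried both marks. The fold used is that of the strongest peak touching a gene, which need not cover most of it. The peaks with the highest folds of the lists, 3.55 for H3K27me1 and 3.88 for H3K27me3, touched no marked gene. Of the 10 marked genes with the highest H3K27me1 fold, 10 lay in the windows and 6 were also marked by H3K27me3. Of the 10 with the highest H3K27me3 fold, 9 lay in the windows and 9 were also marked by H3K27me1. The top 10 of both marks had 6 genes in common, namely AT5G30490, AT5G26749, LCR40 (AT2G14935), AT3G32130, AT3G42148 and AT2G14500. The first of them led both rankings. AT5G30490 lay 100% under H3K27me1, in a peak on chromosome 5 from 11610577 to 11615276 with a fold of 2.58 and a −log10 q of 22.9. H3K27me3 covered 57.8% of it, and its strongest H3K27me3 peak ran from 11610671 to 11611939 with a fold of 3.30 and a −log10 q of 24.6. The H3K27me3 share of this gene was 5.56% when only peaks with a −log10 q of at least 5 were kept. The peak of fold 3.30 thus covered no more than that, and weaker peaks made up the rest. LCR40, which encodes a small cysteine-rich peptide of the defensin-like type, lay 100% under both marks. Its H3K27me1 peak ran on chromosome 2 from 6427684 to 6433537 (fold 2.33) and its H3K27me3 peak from 6427826 to 6433432 (fold 2.36). AT3G32130 also lay 100% under both, with an H3K27me1 peak on chromosome 3 from 13126559 to 13133648 (fold 2.30) and an H3K27me3 peak from 13126667 to 13129300 (fold 2.70). These calls rested on the broad lists. Under the narrow lists 1 of the 10 leading H3K27me1 genes, AT2G14500 with 52.8% covered, and 0 of the 10 leading H3K27me3 genes were still covered over at least 50%. The narrow lists covered 6.74% of LCR40 for H3K27me1 and 0% for H3K27me3, and 2.47% and 1.02% of AT3G32130.

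Of the 8 remaining leading genes, 5 were marked by 1 mark alone and 3 by both. AT5G38930 lay 100% under an H3K27me1 peak on chromosome 5 from 15583126 to 15586529 (fold 2.22) and had 0% under H3K27me3. AT3G45555 lay 100% under H3K27me1 (fold 2.34) and 0.779% under H3K27me3, and AT2G05590 60.6% (fold 2.32) and 7.97%. The H3K27me3 peaks reaching into these genes had folds of 2.31 and 2.62 and −log10 q of 12.8 and 19.3. VPS2.1 (AT2G06530), a subunit of the ESCRT-III membrane remodelling complex, lay 100% under H3K27me1 (fold 2.27) and 35.2% under H3K27me3 (fold 2.24, −log10 q of 8.32). In the other direction, AT5G37930 lay 100% under H3K27me3, in a peak on chromosome 5 from 15101543 to 15107047 (fold 2.27), and 7.02% under H3K27me1. The H3K27me1 peak reaching into it had a fold of 2.12 and a −log10 q of 8.47. Of the 5 genes marked by 1 mark alone, only AT5G38930 had no peak of the other mark reaching into it. Of those marked by both, AT4G08868 was covered 92.3% by H3K27me1 and 100% by H3K27me3 (fold 2.31). AT5G27930 was covered 81.8% and 50.8% (fold 2.26), with the H3K27me3 share at 12.2% among peaks with a −log10 q of at least 5. UMAMIT45 (AT3G28100), of a family of amino acid transporters, was the only gene of either top 10 outside the windows. It was covered 57.8% by H3K27me1 and 56.9% by H3K27me3 (fold 2.14 and 2.26).

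None of the 13 fixed gene lists stood apart from other genes in the share of marked members. Of 26 Fisher exact tests 0 passed the threshold, with 0 raw p-values under 0.05 and a lowest adjusted p of 1. The lists were small, and 3 marked members were needed for a raw p under 0.05 in lists of 7, 11 and 15 genes. They were too small to show a shortage: in the largest, 0 of 17 sperm genes marked by H3K27me3 gave a Fisher exact p of 0.62. Over all 158 listed genes, H3K27me1 marked 1 and H3K27me3 marked 4, of which 3 were under H3K27me3 alone and 0 under H3K27me1 alone (exact McNemar p = 0.25). With 3 such genes the exact test cannot give a p below 0.25. The pooled counts of 1 and 4 were low against the 5.49% and 5.67% marked among all genes. Those shares make no allowance for gene length, and whether the pooled counts fell short was not tested. Single lists held at most 2 genes under 1 mark alone, where the smallest exact p is 0.5, so no difference between the marks could have passed within a list.

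The embryo regulators had 2 of 11 members marked by H3K27me3 and 0 of 11 by H3K27me1 (Fisher exact p = 0.13 for H3K27me3, adjusted p = 1). DOG1 (AT5G45830), a regulator of seed dormancy, was covered 76.4% by H3K27me3 and 0% by H3K27me1. Its peak lay on chromosome 5 from 18588494 to 18591013, with a fold of 1.50 and a −log10 q of 1.54. WOX2 (AT5G59340), a homeobox gene of the early embryo, was covered 57.6% by H3K27me3, in a peak from 23934064 to 23940056 on chromosome 5 (fold 1.55, −log10 q of 2.0), and 0% by H3K27me1. Neither gene kept any H3K27me3 coverage among peaks with a −log10 q of at least 5. LEC1 was covered 45.6% by H3K27me1 and 44.6% by H3K27me3, and LEC2 0% by both. WOX8 and ABI3, which the naming rule did not pick, were covered 27.4% and 5.21% by H3K27me3 and 0% by H3K27me1. Of the YUC genes of auxin synthesis, 1 of 11 was marked by H3K27me3 and 0 by H3K27me1. That gene was YUC6 (AT5G25620), covered 64.2% by H3K27me3 in a peak on chromosome 5 from 8934485 to 8937398 (fold 1.84, −log10 q of 5.79) and 29.7% by H3K27me1. The narrow lists covered 20.8% of it by H3K27me3, which ended its call. YUC2 was covered 8.71% by both. Among vegetative cell genes of pollen, 1 of 12 was marked by each mark. It was the pollen MADS-box gene AGL30 (AT2G03060), covered 54.8% by H3K27me1 and 53.3% by H3K27me3, and at 0% for both among peaks with a −log10 q of at least 5. ANX2, a receptor kinase of the pollen tube, was covered 5.78% and 5.16%.

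The other 10 lists had 0 marked members for both marks. Among 17 sperm genes, GEX1 was covered 15.7% by H3K27me3 and 0% by H3K27me1, DAN1 6.17% and 4.57%, and DMP8, which encodes a sperm membrane protein needed at fertilisation, 0% by both. DMP9 and GEX3, which the naming rule did not pick, were covered 6.15% and 1.36% by H3K27me3 and 0% by H3K27me1. Among 14 floral organ identity genes, AG was covered 42.7% by H3K27me1 and 40.4% by H3K27me3, SEP3 30.1% and 27.9%, and STK 9.68% and 34.0%. Among 14 flowering time genes, H3K27me3 covered 36.8% of TFL1 and 18.01% of MAF2, both at 0% for H3K27me1. FLM, a MADS-box repressor of flowering, was covered 21.3% by H3K27me1 and 16.3% by H3K27me3, and its relative MAF5 15.7% and 0%. Among 15 imprinted endosperm genes, HDG3 was covered 26.0% by H3K27me1 and 26.3% by H3K27me3. MEA, a Polycomb methyltransferase that is also one of those genes, was covered 19.96% and 20.8%. The other Polycomb list members with the most coverage, of 12 in that list, were VIN3 with 9.49% and 10.5% and VRN2 with 10.4% and 0%. Of 7 demethylases and monomethyltransferases of H3K27, the demethylase REF6 had 1.28% under H3K27me3, and JMJ30 and JMJ32 0% under both. Among 15 meristem genes, KNAT1 was covered 35.1% by H3K27me1 and 5.98% by H3K27me3, KNAT6 11.1% and 0%, CUC1 0% and 24.2%, and WOX4 0% and 18.2%. Among 11 seed storage genes, the cruciferin gene CRB was covered 0% and 39.0%, and the oleosin gene OLEO2 36.8% and 37.0%. Among 11 photosynthesis genes, LHCB2.1 was covered 18.6% and 0%, RBCS2B 12.7% and 10.6%, and RBCS3B 0% and 5.32%. Among 12 housekeeping genes, UBQ10 was covered 23.9% and 25%, ACT2 0% and 8.70%, and CB5E 5.84% and 0%.

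When 1 covered base was enough, floral organ identity genes were reached in 7 of 14 cases by H3K27me1 (Fisher exact p = 0.023) and 8 of 14 by H3K27me3 (p = 0.013), but neither passed after adjustment (adjusted p = 0.297 for both, 0 of 26 tests). Sperm genes were reached in 1 of 17 cases by H3K27me1 (Fisher exact p = 0.144) and 4 of 17 by H3K27me3 (Fisher exact p = 1), against 22.7% and 26.0% of other genes. Over all listed genes, 25 were reached by H3K27me3 alone and 10 by H3K27me1 alone (exact McNemar p = 0.017). H3K27me3 alone thus made up 71.4% of listed genes under a single mark, against 62.3% among all genes under a single mark, a difference that did not pass (Fisher exact p = 0.297).

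**Figure D3:**
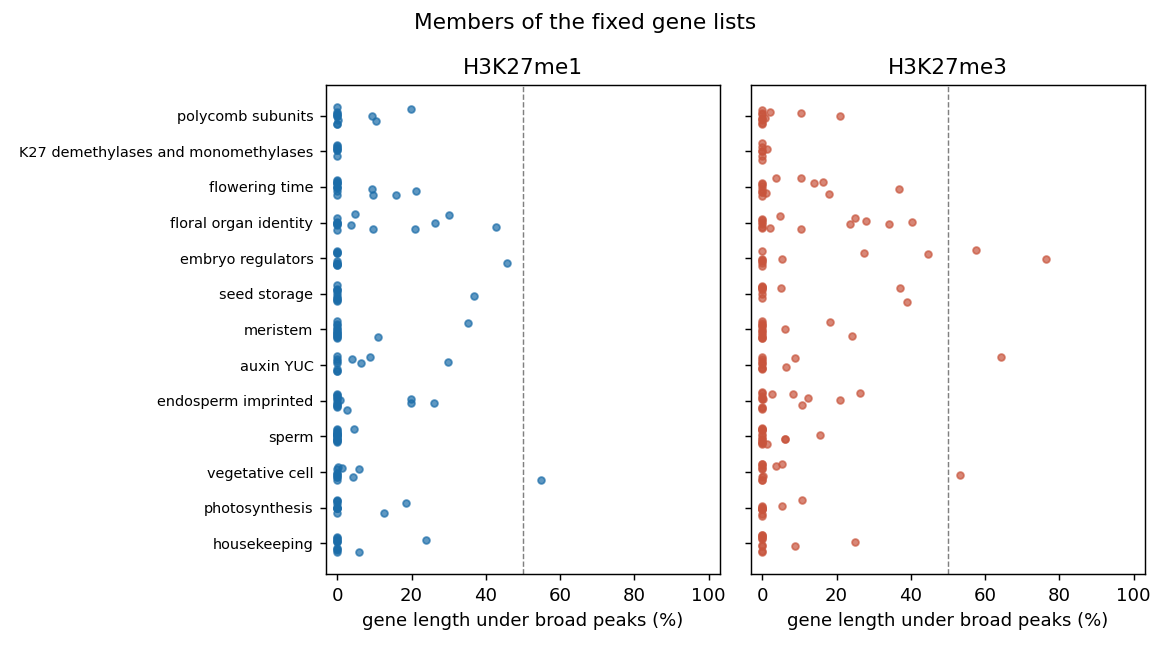
Percent of each gene's length under broad peaks (x axis) for members of the 13 gene lists (rows), with H3K27me1 in the left panel and H3K27me3 in the right. Each point is a gene, jittered vertically, and the dashed line at 50% is the threshold for a marked gene, passed by 1 gene for H3K27me1 and 4 for H3K27me3.

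Genes of small structural RNAs were covered more often than shifted peaks would give, but their ratios did not exceed those of sequence beside genes. The shifts also place these genes inside protein-coding genes, which peaks of both marks avoid. Sequence within 1 kb of a gene held 1.97 (H3K27me1) and 2.02 (H3K27me3) times the shift means of peak territory, and sequence 1 to 5 kb away 2.61 and 2.52 times. Those are shares of bases and the values below are shares of genes, so the comparison is rough. At least 50% of the length lay under H3K27me3 in 29.4% of 625 tRNA genes (1.75 times the shift mean, adjusted permutation p = 0.0028) and under H3K27me1 in 24.2% (1.44 times, adjusted p = 0.004). Of 287 snoRNA genes, 32.4% were marked by H3K27me3 (1.89 times, adjusted permutation p = 0.0028) and 26.8% by H3K27me1 (1.56 times, adjusted p = 0.026). H3K27me3 marked 19.5% of 3480 lncRNA genes (1.16 times, adjusted permutation p = 0.0028), and H3K27me1 17.8% (1.05 times, adjusted p = 0.32). H3K27me1 marked 21.3% of 926 transcribed pseudogenes (1.28 times, adjusted permutation p = 0.026), and H3K27me3 18.1% (1.12 times, adjusted p = 0.29). Other pseudogenes, 3917 in number, were marked less often by H3K27me3 (5.51%, 0.39 times, adjusted permutation p = 0.004), and their H3K27me1 share of 8.63% did not pass (0.58 times, adjusted p = 0.11). This class was taken as annotated, and whether it includes transposable element genes was not examined. Of 326 miRNA genes, 21.5% were marked by H3K27me3 and 18.1% by H3K27me1, neither past the threshold (adjusted permutation p = 0.077 and 0.72). Protein-coding genes were marked at 0.38 and 0.41 times the shift means by H3K27me1 and H3K27me3 (adjusted permutation p = 0.0028 for both). Many tRNA genes have near-identical copies, and how reads from such copies were placed is not given in the sources used here.

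**Figure D4:**
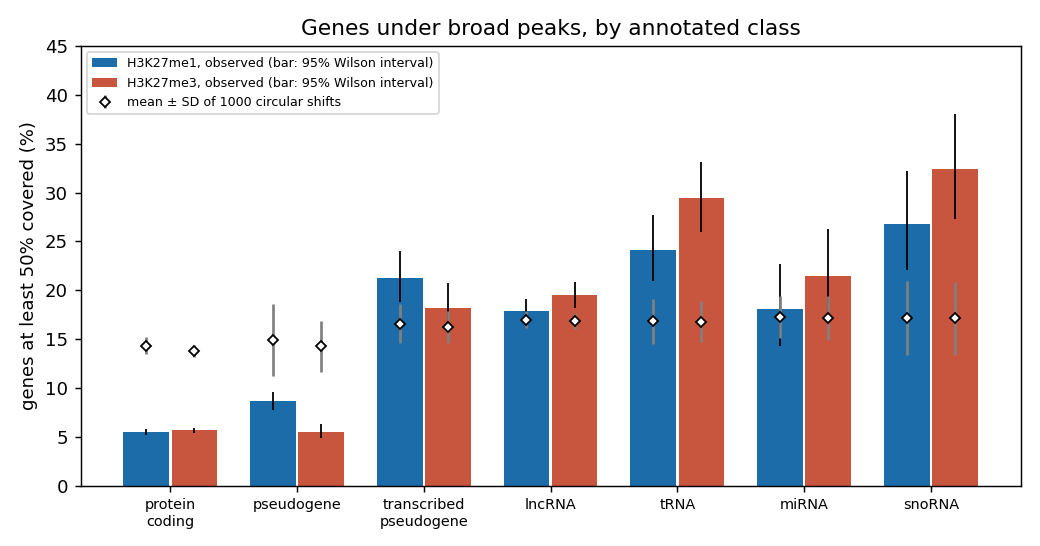
Percent of genes with at least 50% of their length under broad peaks (y axis) for 7 annotated gene classes (x axis), with H3K27me1 in blue and H3K27me3 in red. Black bars are 95% Wilson intervals, and diamonds with grey bars are the mean and SD of 1000 circular shifts. Both tRNA and snoRNA bars lie above the shift means, and protein-coding bars of 5.49% and 5.67% lie below. The shifts make no allowance for the avoidance of protein-coding genes by peaks.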

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

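The alternative of shifting peaks within arms and pericentromeres separately was chosen for the protein-coding gene share after its result was seen; the other alternatives were planned. No paired analysis was possible because each mark had 1 peak list and no value per sample, and leaving out replicates was not possible for the same reason. Counting peaks around gene starts was not run, since the gene table gives no strand. Under the narrow lists, the −log10 q minimum of 5, the 50% with the highest fold and gap merging, the shared length (4.42 to 13.9 times the shift mean), the pericentromere ratios (1.55 to 3.05) and the gene shares (0.19 to 0.35) kept their direction and stayed past the threshold. Shifts within arms and pericentromeres separately gave 3.70 for the shared length and 0.39 for both gene shares, lists of equal length gave 4.52, and windows 1 Mb longer on each side gave 1.80 and 1.55, with no call changed. No list test passed under any setting. Merging across gaps of up to 500 bp changed no value, so it tested nothing.

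Sizes moved with the setting, as fewer or smaller peaks were kept, and the order of the marks in marked genes, 1507 and 1555 with no difference past the test (exact McNemar p = 0.14), was a higher H3K27me1 count under the 3 following settings, past the test in the first 2 but not in the last (exact McNemar p = 0.72). The narrow lists covered 7.19 Mb (H3K27me1) and 5.94 Mb (H3K27me3), with median widths of 580 and 540 bp, median folds of 1.94 and 2.07, and 84 and 53 marked genes. A −log10 q of at least 5 left 2331 and 1609 peaks over 6.27 and 3.49 Mb, with widths of 1836 and 1518 bp, folds of 1.80 and 1.95, and 465 and 238 marked genes. The lists were called separately, so that cutoff need not be equally strict for both marks. The 50% with the highest fold held 5949 and 6464 peaks over 12.3 and 11.7 Mb, with widths of 1398 and 1290 bp, folds of 1.68 and 1.75, and 941 and 930 marked genes. With 1 covered base enough, 6219 and 7143 genes were reached. At 50% reciprocal overlap, 64.7% of H3K27me1 and 59.5% of H3K27me3 peaks were shared. Windows 1 Mb shorter on each side gave an H3K27me3 ratio of 1.33 (permutation p = 0.056), which ended its call; the cause was not tested. Of 104 coverage values of named genes, 27 crossed 50% with the narrow lists, which kept 1 of 10 leading genes for H3K27me1 and 0 of 10 for H3K27me3, and 6 with each stricter selection of broad peaks. Most of the 104 values were under 50% to begin with and could not be lost. The only call of a named gene that the narrow lists kept was H3K27me1 on AT2G14500. Depth is unknown, so weak peaks near the threshold are the least certain.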

Other observations

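The families were picked out, and the tests of weak peaks and of stretches under 1 mark alone chosen, after results were seen; the matched random lists for the LCR and SCRL genes were set before theirs, and those of LCR and SCRL apart on length after. Among 58 symbol families of at least 20 members (2281 genes), 3 were marked more often than other genes by H3K27me1 and 4 by H3K27me3 (Fisher exact tests with Benjamini-Hochberg adjustment over both marks). Of the LCR genes, which encode cysteine-rich defensin-like peptides, 30 of 81 (37.0%) were marked by H3K27me1 (Fisher exact, adjusted p = 1.3e-15) and 26 of 81 (32.1%) by H3K27me3 (Fisher exact, adjusted p = 1.0e-11). Of the related SCRL genes, 7 of 27 (25.9%) were marked by H3K27me1 (Fisher exact, adjusted p = 0.0064) and 9 of 27 (33.3%) by H3K27me3 (Fisher exact, adjusted p = 0.00021). Arabinogalactan protein (AGP) genes, which encode cell surface proteoglycans, were marked in 9 of 30 cases by H3K27me1 (Fisher exact, adjusted p = 0.00037) and 10 of 30 by H3K27me3 (Fisher exact, adjusted p = 0.00011). RALFL signalling peptide genes were marked in 10 of 32 cases by H3K27me3 (Fisher exact, adjusted p = 0.00016), while 5 of 32 for H3K27me1 did not pass (Fisher exact, adjusted p = 0.28). Against 10000 random lists of genes of like length, the AGP genes lay at percentile 99.5 for H3K27me1 and 99.8 for H3K27me3, and the RALFL genes at 47.6 and 98.2. The SCRL genes alone lay at 88.1 and 97.9. These ranks are given for families past the Fisher tests, which make no allowance for length. A family that did not pass could rank as high. The UMAMIT genes, with 5 of 44 marked by each mark, lay at 99.7 for both. The cytochrome P450 (CYP) genes were marked less often, 2 of 229 by H3K27me1 (Fisher exact, adjusted p = 0.0057) and 0 of 229 by H3K27me3 (Fisher exact, adjusted p = 0.00011). The EMB genes with capital symbols, named for embryo-defective mutants, were marked in 0 of 112 cases by both (Fisher exact, adjusted p = 0.032 for both). Genes with the lower-case symbol emb were counted apart. Of these 48, H3K27me1 marked 0 and H3K27me3 marked 1 (Fisher exact, adjusted p = 0.52 and 0.86). Against random lists of like length the CYP genes lay at percentile 1.84 for H3K27me1 and 0.04 for H3K27me3, and the EMB genes at 1.5 and 1.58, with 3.47 and 3.38 marked genes in the EMB-matched lists on average.

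Of the 238 tRNA genes on chromosome 1, 13.4% were marked by H3K27me1 and 19.7% by H3K27me3. The shares were 21.1% and 22.1% of 95 on chromosome 2, 34.8% and 38.04% of 92 on chromosome 3, 31.2% and 37.7% of 77 on chromosome 4, and 35.0% and 42.3% of 123 on chromosome 5. Differences between chromosomes were not tested.

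The first pattern weighed is that both marks lie at the same places. Coincidence in pericentromeres only was argued against, since outside the windows the marks shared 8.58 Mb, 5.15 times the mean of shifts within the arms (permutation p = 0.001). The windows were coarse, and some sequence outside them was as densely covered as that inside. The 500 kb bin centred on 0.25 Mb of chromosome 2 lay 34.6% under H3K27me1 and 35.2% under H3K27me3. Shifts within the arms made no allowance for such flanks. A background common to both lists stays open for the shared places, and it may account for them: 3.48% at most of the strongest 10% of peaks lacked the other mark, under the 5% set in advance. Chance crossings of the threshold over such a background, in lists of like sensitivity, would place the stretches under either mark alone alike. A mean difference of 36.3 percentage points in window share argued against this (SD 7.70, 26.6 to 42.7 over 5 chromosomes, exact sign-flip p = 0.0625). The largest of 1000 random exchanges of the marks within 500 kb bins was 11.7 against 36.7 over all chromosomes (permutation p = 0.001). Neighbouring bins were alike, so that permutation p may be too small. Most of these stretches, by number, were parts of peaks that also held the other mark. The difference therefore concerns how far peaks extended as well as separate places. Depth is unknown, and lists of unequal sensitivity over a common background could also place such stretches differently. That case, and a background that differs between the marks, were not tested and stay open. Antibody cross-reaction and true presence of both marks in the same regions were not tested, and no value of the inputs was analysed here that would set them apart from a common background.

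The second pattern is that peaks of both marks avoid protein-coding genes. A pull of peaks to gene-poor pericentromeres was argued against, since outside the windows the gene share was still 0.34 times the mean of shifts within the arms for H3K27me3 and 0.31 times for H3K27me1 (permutation p = 0.001 for both). The densely covered flanks outside the windows were included here too. Weak peaks placed by chance would give about the shifted share and so could not make the avoidance. The test chosen for them therefore decides nothing. In it, the ratio among peaks with a −log10 q of at least 5 was 0.28 for H3K27me1 and 0.27 for H3K27me3, below the 0.32 and 0.35 of all peaks. Those peaks also lay more in the windows, at 3.05 and 2.79 times the shift means, and these shifts ran over whole chromosomes. Base composition and the preference of micrococcal nuclease, which could differ between genes and the sequence beside them, were not tested. No biological explanation was tested.

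The third pattern is the coverage of the defensin-like LCR and SCRL genes, 108 in all, of which 37 (34.3%, Wilson 95% interval 26.0 to 43.6%) were marked by H3K27me1 and 35 (32.4%, 24.3 to 41.7%) by H3K27me3. Their median length was 584.5 bp, and 14.8% lay in the windows. Pooled, they lay at percentile 100 of 10000 random lists matched on length for both marks (16.4% and 16.8% marked on average), and at 100 and 99.98 of lists matched also on distance to neighbours. This argues against short length and wide spacing as the whole explanation for the LCR genes, which alone lay at percentile 99.985 or above for length and 99.855 or above for both, but it stays open for the SCRL genes, at 88.1 and 97.9 for length and 85.8 and 96.3 for both. The families were picked for their high coverage and some members may lie in clusters and share peaks, so these percentiles overstate the evidence, and no biological explanation was tested.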
